A study of Homo sapiens with 6 samples.

How the data were processed

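Polyadenylated RNA was read at its 3' ends in 6 libraries from H9 cells, an established human embryonic stem cell (hESC) line. The 3 hESC libraries and the 3 libraries of endoderm cells, made from hESCs by 6 days in activin A at 100 ng/ml, each hold 1 library labelled G1, 1 labelled G1/S and 1 labelled S. The endoderm medium held 0% fetal bovine serum on the first day, 0.2% on the second and 2% later, and was changed on day 3. No such steps are recorded for the hESCs, so serum and medium differ along with cell type. The hESC libraries were taken at 0, 2 and 3 h and the endoderm libraries at 0, 3 and 6 h, in that order of phases. The event from which the hours count and the way cells were brought into phase are not given in the sources used here.

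The submitters' processing notes name CASAVA 1.5, Bowtie 0.12.7 and DESeq 1.5.24 with the human builds hg18 and NCBI36, without the role of each. The authors deposited 1 table with a signal value per library for 14686 genomic regions in which read ends gather, each with a position and either a gene symbol or a number for a region without a gene name. The deposited signal values are linear, although the table is named after a variance-stabilising transformation. At a tolerance of 1e-06, 100% of the values in each library are a whole number of reads divided by 1 constant, and that constant equals the median-of-ratios size factor recomputed from the reads. The design, written before the data were examined, assumed values on a variance-stabilised log scale and named log2(value + 1) for linear values, so log2(value + 1) was used. A fold change on this scale understates the change of weakly expressed genes.

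The recovered reads per library number 4972977, 4194957 and 6203079 in hESC G1, G1/S and S, and 5389666, 3205025 and 2502792 in endoderm G1, G1/S and S. The value of 1 read lies between 0.591 in hESC S and 1.71 in endoderm S, and a count of 0 allows a value of up to 1.77 to 5.13 (3 reads). Counting intervals given for single libraries are 95% intervals. They and the floors cover counting error only, since amplified reads are not independent molecules. The fewest reads any region has over the 6 libraries is 60, and the median is 259.

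Of the regions, 10368 carry a gene name and 4318 do not. The named regions hold 9588 distinct names, of which 7981 matched a current symbol, 1220 an older symbol, 23 several genes and 364 none. A name with several regions (719 of them) was represented in lists and in the choice of named genes by the region with the highest mean. Gene annotation of the build used for the positions was not at hand, so no exon or untranslated region is given, and positions are printed as deposited. GC content was taken from the last 500 bases of the transcripts in a later annotation, for 95.8% of the named regions, so checks of GC content were run on regions with a gene name only. No column of values was left unused.

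Regions were kept where log2(value + 1) was at least 1 in at least 3 of the 6 libraries, which left 14657 and removed 29. The model had a term for cell type and a term for phase and was fitted with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3. It has 2 residual degrees of freedom and a prior of 5.46. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. No library has a replicate of the same type and phase, and all come from 1 passage, so these p-values measure the spread among these libraries only. The phase terms assume that a phase does the same in both cell types. Means are given ± SD over the 3 libraries of a type, which differ in phase. Within a cell type each phase has 1 library, so values and counting intervals are given and no test was run.

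On simulated reads with the real means and library sizes, in a set of 14657 regions, the endoderm comparison recovered 2.99% of the regions changed 2-fold, 71.6% of those changed 4-fold and 92.4% of those changed 8-fold, with 4 calls among 14457 unchanged regions. The S against G1 comparison recovered 1.49%, 34.3% and 87.9%, with 3 such calls. The changed regions were drawn from the better expressed ones only, so recovery among weakly expressed regions was not measured.

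Gene lists fixed before the data were examined were tested with camera in limma at a preset correlation of 0.01, adjusted over 20 lists. They cover pluripotency, definitive endoderm, later endoderm and hepatic genes, mesoderm, neuroectoderm, trophoblast and extraembryonic genes, stromal and mesenchymal genes, epithelial genes, G1/S and DNA replication, G2/M, G1 cyclins with their kinases and inhibitors, histones, nodal and activin targets, the Wnt pathway, immediate early genes, p53 targets, hypoxia and glycolysis, cholesterol biosynthesis, DNA methylation and chromatin, and the unfolded protein response. A further list, of mitochondrially encoded genes, had 0 of 13 members under the names used in the table. With an estimated correlation camera works with the 2 residual degrees of freedom of the model, so a list could hardly pass whatever its correlation. Wnt pathway genes, with an estimated correlation of -0.0556, went from camera p = 0.00049 to camera p = 0.0668 between the types. A call lost under that setting therefore does not show that correlation among members accounts for it. Within a cell type, a list's median S minus G1 difference was set as a percentile among 10000 random lists of the same size matched on mean level. Random lists take members to be unrelated, and the correlation estimated by camera reaches 0.341 in nodal and activin targets, so a percentile is a rank and not a test.

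The genes named between the cell types are drawn from the 10 largest rises and 10 largest falls past the threshold with the same direction in each phase, the 3 members of each list with the largest difference, and a fixed set of pluripotency, endoderm and cell-cycle genes. For S against G1 in both cell types the 10 smallest p-values in each direction are named, and extending this rule to G1/S against G1 was chosen after seeing the data. Within a type the rule takes the 8 largest differences in each direction among genes with a mean log2 level above 6.06 whose G1/S value lies between G1 and S, and 3 members of each of 5 cell-cycle and early-response lists. Not every gene these rules pick is printed, except for S against G1 over both types and for the 8 largest differences within a type. Genes outside these rules are said to be chosen after their values were seen.

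Alternatives were other filters, quantile normalisation, median centring, eBayes without trend or with the robust option, a fold minimum of 2, the mean over a gene's regions, each library left out, no phase term, and an estimated correlation in camera. Chosen after seeing the data were a pseudocount of 10, removal of each library's trend on GC content, leaving out both G1/S libraries, and count tests on the recovered reads. Of the count tests, the quasi-likelihood test of edgeR 4.0.16 calls 1990 regions between the cell types and DESeq2 1.42.0 calls 2780. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.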

Results

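The series compares the transcripts of human embryonic stem cells and of endoderm cells derived from them as the cells pass from G1 into S phase. Libraries of 3' read ends were made from H9 hESCs in G1, G1/S and S (3 libraries) and from day 6 endoderm in the same phases (3 libraries). The libraries hold between 2502792 reads (endoderm S) and 6203079 reads (hESC S). Values are read counts divided by a size factor per library, called signal here.

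The comparison of endoderm with hESCs asks which transcripts mark the differentiated state. Regulators of endoderm identity stood far above their hESC level in each phase. SOX17, a transcription factor that directs endoderm formation, rose from 2.45 ± 1.85 to 155 ± 44.4 (mean signal ± SD, n = 3 per type), and GATA6, a zinc finger factor of the same program, rose from 5.67 ± 2.21 to 209 ± 78.2. FOXA2, a pioneer factor of endoderm, rose from 4.06 ± 3.70 to 85.7 ± 29.6, and the chemokine receptor CXCR4, used to sort definitive endoderm, from 22.4 ± 14.6 to 524 ± 208. The secreted nodal antagonists LEFTY2 and CER1 rose to 12540 ± 5021 and 2017 ± 453 from 591 ± 183 and 99.5 ± 32.1.

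The largest rises on the log2(value + 1) scale were those of DIO3, an enzyme that inactivates thyroid hormone (log2 difference 5.92 ± 0.33 SE, limma adjusted p = 0.00118), and FGF17, a fibroblast growth factor (5.60 ± 0.25, limma adjusted p = 0.000677). That scale shrinks the differences of genes with few reads, such as SOX17 with 6, 1 and 3 in hESC G1, G1/S and S. DIO3 rose from 129 ± 62.0 to 7609 ± 2425 and FGF17 from 310 ± 112 to 15090 ± 5150. SOX17 followed at 5.59, the retinoid receptor RXRG at 5.53, the organizer factor GSC at 5.26, GATA6 at 4.97, the signalling protein SHH at 4.86, the chemokine receptor CXCR7 at 4.86, the forkhead factor FOXI1 at 4.85 and the matrix protein FREM1 at 4.76. On the log2(value + 1) scale HES3, a basic helix-loop-helix factor, fell most, from 207 ± 107 to 5.84 ± 4.73 (log2 difference -5.16 ± 0.61 SE, limma adjusted p = 0.00424). The other large falls were those of ESPNL (-4.88), ERAF (-4.88), MYO7A (-4.85), SIT1 (-4.84), PYY (-4.76), CABYR (-4.73), TCL1B (-4.72), LTB (-4.66) and GDPD2 (-4.65), which stood between 42.0 and 209 in hESCs and between 0.571 and 8.64 in endoderm. These rest on few endoderm reads (ESPNL 4, 0 and 0, ERAF 3, 0 and 0, CABYR 0, 0 and 1 in G1, G1/S and S), so the added 1 shapes their differences and their order.

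**Figure D1:**
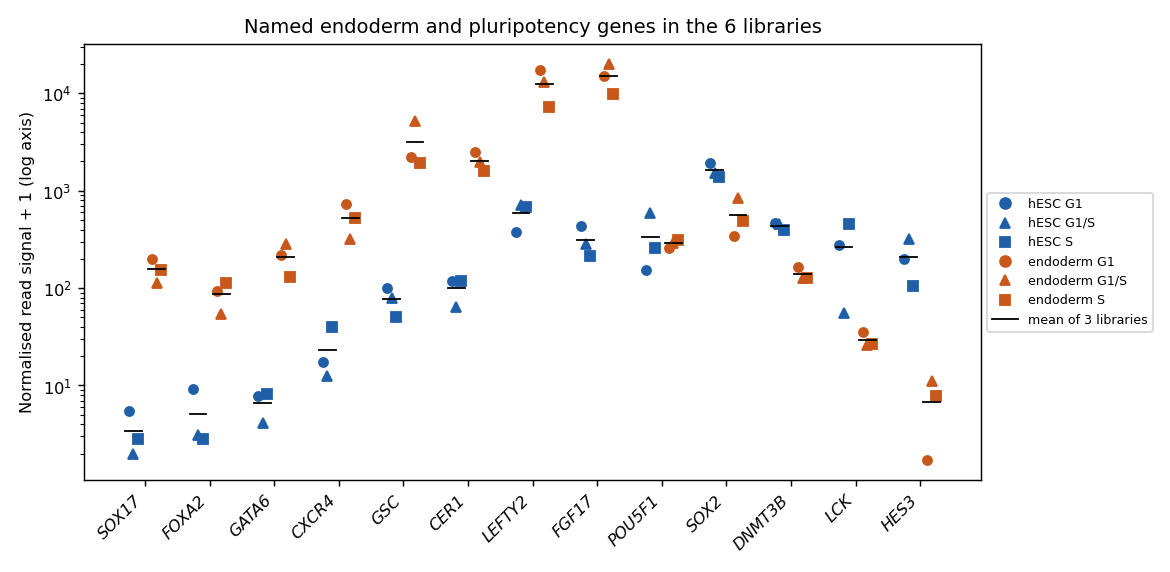
Signal + 1 on a log axis for named genes in each of the 6 libraries, coloured by cell type and shaped by phase, with the mean of 3 libraries as a bar. SOX17, FOXA2, GATA6 and CXCR4 are higher in every endoderm library than in any hESC library, while POU5F1 overlaps between the types.

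In all, 2125 of 14657 regions passed the threshold, 1011 higher and 1114 lower in endoderm, and 5016 had an unadjusted p under 0.05. The G1/S libraries weigh heavily in this count, which is 419 without the hESC G1/S library, 571 without the endoderm one and 415 without both. It is 975 without hESC S, 1200 without endoderm S and 984 with a filter that tests 7343 regions. The side with more regions depends on the setting too, as that filter gave 546 higher and 438 lower and edgeR 816 and 1174. Of 68 named genes past the threshold, 34 stayed past it whichever library was left out, among them SOX17, FOXA2, GATA6, CXCR4, CER1, LEFTY2, DIO3, FGF17, GSC and HES3.

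Of 18 measured members of the definitive endoderm list, 16 rose and none fell (18 and 0 adjusted over the list alone), with a median log2 difference of 4.32 (camera adjusted p = 8.14e-18, and adjusted p = 0.498 with an estimated correlation). Of 9 later endoderm and hepatic genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone; median 1.25, adjusted p = 0.0125, and adjusted p = 0.498 with an estimated correlation). The lipoprotein genes APOA1 and APOA2 rose from 247 ± 71.6 to 3235 ± 1776 and from 147 ± 6.55 to 2073 ± 1021. TTR, a thyroid hormone carrier made in liver, fell from 15.2 ± 0.43 to 0 reads in each endoderm library (limma adjusted p = 0.0305), a call that was kept in 1 of the 6 fits with a library left out. The hepatic list itself did not pass without either G1/S library or without the intensity trend, where 3 of its members rose and 2 fell.

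Pluripotency genes went both ways. Of 19 measured, 1 rose and 6 fell (3 and 7 adjusted over the list alone; median -0.14, adjusted p = 0.415). Without the intensity trend 1 rose and 1 fell, as without both G1/S libraries, so the excess of falls depends on the setting. SOX2, a core pluripotency factor, fell from 1615 ± 272 to 557 ± 258 (log2 difference -1.62 ± 0.33 SE, limma adjusted p = 0.0214). DNMT3B, a de novo DNA methyltransferase, fell from 438 ± 40.5 to 139 ± 23.1, and the kinase LCK from 263 ± 203 to 28.4 ± 5.33. POU5F1, the octamer factor of pluripotent cells, was at 336 ± 231 in hESCs and 287 ± 28.5 in endoderm (log2 difference -0.01 ± 0.37 SE, limma adjusted p = 0.989). Its hESC values were 153.6 in G1, 595.5 in G1/S and 259.3 in S. GDF3, a ligand of the TGF-beta family, rose from 8.93 ± 3.22 to 128 ± 85.0. NANOG has no region among those kept.

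Several signalling genes rose in endoderm. Activin A is recorded for endoderm only, so its effect on nodal and activin targets cannot be told apart from that of cell type. The list of those targets shares LEFTY2 and CER1 with the definitive endoderm list and GDF3 and TDGF1 with the pluripotency list. Of 15 nodal and activin targets 7 rose and none fell (10 and 2 adjusted over the list alone; median 1.06, camera adjusted p = 0.000167, and adjusted p = 0.505 with an estimated correlation), against 3 and 0 without both G1/S libraries. Of 12 Wnt pathway genes 4 rose and 1 fell (6 and 1 adjusted over the list alone; median 1.66, adjusted p = 0.00245, and adjusted p = 0.498 with an estimated correlation). The receptors FZD8 (4.25) and FZD5 (3.60) and the transcription factor SP5 (4.21) were the largest rises there, and the list did not pass with the stricter filter (adjusted p = 0.197). Of 21 immediate early genes, which respond first to growth signals, 10 rose and none fell (11 and 0 adjusted over the list alone; median 1.20, adjusted p = 9.04e-05, and adjusted p = 0.498 with an estimated correlation). The rises number 4 without the intensity trend and 0 without both G1/S libraries. Serum and medium differed along with cell type, so their effect on these genes cannot be told apart from it. NR4A1 rose from 24.2 ± 7.83 to 145 ± 55.3 and KLF6 from 109 ± 68.1 to 513 ± 121. DUSP1 rose by 2.35 on its most abundant region, and the mean over its regions gave -0.74.

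Cell-cycle regulators differed between the types in specific members. Of 20 genes in the list of G1 cyclins, kinases, inhibitors and pocket proteins, 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.82, adjusted p = 0.0169, and adjusted p = 0.498 with an estimated correlation), and the list did not pass without either G1 library. The inhibitors CDKN1C and CDKN2A rose from 168 ± 42.3 to 730 ± 224 and from 34.5 ± 13.1 to 204 ± 137, and the S-phase factor E2F3 from 2.84 ± 0.41 to 47.8 ± 29.9. CDKN1A, the p53-induced inhibitor, fell from 1410 ± 898 to 486 ± 167 (limma adjusted p = 0.0344), and MYC rose from 6.27 ± 0.22 to 26.5 ± 4.45 (limma adjusted p = 0.0443). The CDKN1A call was kept in 2 and the MYC call in 0 of the 6 fits that leave out 1 library. The D cyclins and cyclin E1 did not pass, with log2 differences of 0.48 ± 0.28 (SE) for CCND1, 1.24 ± 0.38 for CCND2, -0.02 ± 0.24 for CCND3 and -0.38 ± 0.26 for CCNE1, nor did CDKN1B (1.35 ± 0.60) or the origin-licensing factor CDC6 (-1.23 ± 0.39). CCND1 and CDC6 passed without either G1 library, at 0.78 and -1.49.

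Of 46 G1/S and DNA replication genes, 2 rose and none fell (0 and 0 adjusted over the list alone; median -0.09, mean 0.05, adjusted p = 0.993), the 2 being E2F2 (1.93) and the helicase subunit MCM6 (1.86), whose calls were kept in 2 and 3 of the 6 fits with a library left out. None of 32 G2/M genes passed (0 and 0 adjusted over the list alone; median 0.21, adjusted p = 0.695). None of 7 histone genes passed either (0 and 0 adjusted over the list alone; median 0.52). Those measured were HIST1H4C, HIST1H1C, H2AFZ, H2AFX, H2AFV, H3F3B and H1FX. Most of the list, mainly other HIST genes, had no region. The libraries hold polyadenylated RNA, so histone transcripts without a poly(A) tail would be missed. The histone list as a whole had adjusted p = 0.0366, and adjusted p = 0.498 with an estimated correlation, and did not pass with any 1 library left out or without the phase term.

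Markers of other lineages went different ways. Of 7 neuroectoderm genes 2 rose and none fell (4 and 0 adjusted over the list alone; median 1.0, adjusted p = 0.0366, and adjusted p = 0.498 with an estimated correlation). The eye and pancreas factor PAX6 rose from 4.92 ± 2.01 to 123 ± 35.3 and the adhesion molecule NCAM1 from 45.9 ± 10.3 to 115 ± 23.7, a call that was kept in 1 of the 6 fits with a library left out. That list did not pass without either G1/S or either S library, with quantile normalisation or without the phase term. Of 6 mesoderm genes 1 rose, TWIST1 (2.62), and none fell (1 and 0 adjusted over the list alone; median -0.26, mean 0.10, adjusted p = 0.993). Of 5 trophoblast and extraembryonic genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; median 0.11, mean -0.23, tested downward, adjusted p = 0.962), with LAMB1 at 1.72, KRT7 at -2.42 and TFAP2C at -2.12 (kept in 2 of those 6 fits). Of 12 stromal and mesenchymal genes 6 rose and 2 fell (6 and 3 adjusted over the list alone; median 0.89, adjusted p = 0.185), with N-cadherin (CDH2) up 2.23 and collagen COL1A1 at -1.78. Without the intensity trend 1 stromal gene rose and 2 fell, and without the phase term 2 rose and 2 fell, so that excess of rises depends on the setting. Of 15 epithelial genes 3 rose and 3 fell (5 and 5 adjusted over the list alone; median -0.07, mean 0.10, tested downward, adjusted p = 0.993). Keratin KRT8 rose from 677 ± 517 to 4234 ± 1568, and E-cadherin (CDH1) had a log2 difference of -2.11 ± 0.39 SE (limma adjusted p = 0.0174, kept in 3 of those 6 fits). Epithelial falls number 1 without the intensity trend and 0 without both G1/S libraries.

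Of 12 unfolded protein response genes 4 rose and none fell (4 and 0 adjusted over the list alone; median 0.49, adjusted p = 0.0366, and adjusted p = 0.517 with an estimated correlation), among them HERPUD1 (3.20, kept in 3 of the 6 fits with a library left out), DDIT3 (2.04) and TRIB3 (2.02). The list did not pass without either G1 or either G1/S library, with quantile normalisation or without the phase term, and none of its members rose without both G1/S libraries. Of 17 p53 targets 2 rose and 3 fell (3 and 4 adjusted over the list alone; median -0.01, adjusted p = 0.744), with MDM2 at -1.71 (kept in 2 of those 6 fits) and FDXR at -1.90. Without the intensity trend 0 rose and 1 fell. Of 17 hypoxia and glycolysis genes 4 rose and 2 fell (4 and 3 adjusted over the list alone; median 0.17, adjusted p = 0.507), with the glucose transporter SLC2A3 at 3.06 and the aldolase ALDOC at -2.18, against 1 and 1 without that trend. Of 18 cholesterol biosynthesis genes none rose and 1 fell, FDFT1 at -1.69, which was kept in 2 of those 6 fits (0 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.326). Of 11 DNA methylation and chromatin genes 1 rose and 2 fell (2 and 3 adjusted over the list alone; median 0.21, mean -0.06, tested downward, adjusted p = 0.962), with the chromatin factor UTF1 down from 1182 ± 413 to 182 ± 89.4.

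**Figure D2:**
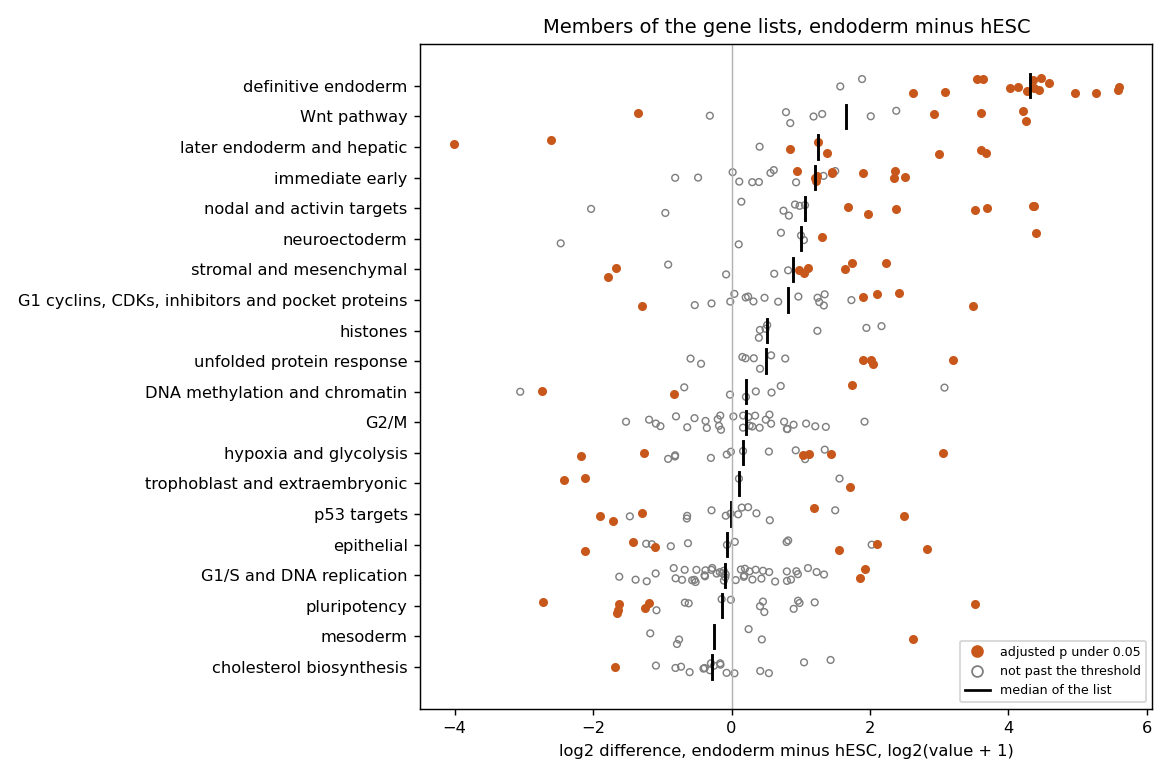
Log2 difference, endoderm minus hESC, on the log2(value + 1) scale for the measured members of the 20 lists. Filled points passed the adjusted threshold of 0.05, open points did not, and bars mark list medians, the highest being definitive endoderm at 4.32.

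The comparison of S with G1 over both cell types asks which transcripts accompany entry into S phase. No region passed, so the following are values. H2AFX, a histone variant tied to DNA damage signalling, was at 18.9 in hESC G1 and 65.6 in hESC S, and at 42.8 and 205.4 in endoderm (log2 difference 1.99 ± 0.44 SE, limma adjusted p = 0.982). The gene with the smallest p, C6orf223, stood at 1.5 and 30.7 in hESCs and 50.4 and 350.9 in endoderm (3.22 ± 0.46 SE). Its hESC G1 value lies below the limit that a count of 0 allows in that library (2.27). TSC22D3, a glucocorticoid-induced factor, had a log2 difference of 1.61, the small GTPase RRAD 2.87, the stress-responsive Cap43 1.41, the imprinted PHLDA2 1.61 and the autophagy receptor SQSTM1 1.28. MCHR1 (2.13), C2orf54 (2.00) and FSIP1 (1.47) had differences in this direction too. On the lower side were WHSC1, a histone methyltransferase (-1.46), RCBTB1 (-2.22), SYT17 (-1.41), the sialyltransferase ST6GAL1 (-1.78), PMPCB (-2.30), GDPD1 (-2.12), ASCC3 (-1.61), ANKRA2 (-1.59), SCNN1D (-1.41) and EFS (-1.27).

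With limma 0 regions passed and 497 had an unadjusted p under 0.05, edgeR called 0, and DESeq2 called 1, C6orf223. The limma count is 201 without the endoderm G1 library. Among lists, histones (the 7 measured genes), immediate early genes and hypoxia and glycolysis genes tested higher in S (camera adjusted p = 0.0256 for each). Neuroectoderm genes did too (adjusted p = 0.0492). G1/S and DNA replication genes (adjusted p = 0.0284) and definitive endoderm genes (adjusted p = 0.0329) tested lower. Each of these lists has adjusted p = 0.591 with an estimated correlation, and each lost its call in at least 1 fit with a library left out. The neuroectoderm list also failed with quantile normalisation and median centring, and the hypoxia list after GC correction.

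The G1/S and G1 libraries were compared in the same way. FOSB, an immediate early gene of the AP-1 family, was at 29.5 in hESC G1 and 246.8 in hESC G1/S, and at 17.3 and 1113 in endoderm (log2 difference 4.48 ± 0.65 SE, limma adjusted p = 0.362). AXUD1 (1.78), NAB2 (2.38), LFNG (2.18), JUNB (2.13) and FOSL1 (1.67) were also higher at G1/S in both types, without a call. RPS27L, a p53-responsive ribosomal protein, was at 970.6 and 167.6 in hESCs and 729.8 and 129.8 in endoderm (-2.51 ± 0.31 SE, limma adjusted p = 0.323), and PABPC1, which binds poly(A) tails, had a log2 difference of -3.01. TOP2A (-2.56) and TYMS (-2.11), genes of the dividing cell, were lower at G1/S too. Not all immediate early genes were higher, as EGR1 was at 75.7 and 28.1 in hESCs and at 87.7 and 16.6 in endoderm. No list passed. The smallest camera adjusted p, 0.0671, was for G1/S and DNA replication genes, TYMS among them, which tested lower at G1/S. Of the 20 genes this rule picks, DESeq2 calls 19, and 12 pass without hESC G1 and 13 without endoderm G1.

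With limma, 0 regions passed for G1/S against G1 (2002 at an unadjusted p under 0.05) and 0 for S against G1/S (1552). edgeR called 0 and 0 and DESeq2 108 and 152. Leaving out hESC G1 gives 329 and 245, endoderm G1 196 and 106, and endoderm S 5 and 83. The G1/S libraries stand apart in GC content, with a rank correlation across regions of 0.43 (hESC) and 0.27 (endoderm) between GC and deviation, against -0.40 to -0.02 in the others. Median centring moves the median log2 difference over all regions from 0.07 to 0.28 for G1/S against G1 and from -0.04 to -0.22 for S against G1/S.

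Within hESCs, each phase has 1 library, so the values are not tested. RPS12, a ribosomal protein gene with many processed copies in the genome among which its reads are uncertain, stood at 55.2 in G1, 147.8 in G1/S and 1447.2 in S (log2 difference S minus G1 4.69, counting interval 4.38 to 5.07). RUFY2 (4.19), PRAM1 (3.58), GPR37L1 (3.19), PPFIA1 (2.89), COX6C (2.83), a region called AIF1 (2.61) and ICHTHYIN (2.61) had the next largest differences among the genes this rule covers. The region called AIF1 lies on chromosome 6 at 2833815 to 2834164, a position that was not compared with that of the gene. TBCA, a chaperone of tubulin folding, was at 2748.5, 538.3 and 240.4 (-3.51, counting interval -3.67 to -3.37), and the initiation factor EIF2S2 at 1922.4, 704.9 and 337.3 (-2.51). MAGI1 (172.5, 44.8 and 20.7), DSTN (-2.90), MPHOSPH6 (-2.64), NTM (-2.59) and BAT2 (-2.54) were lower in S as well. The growth factor PDGFB was at 1302.8, 751.7 and 257.5, and the kinase CDK2 at 780, 613.2 and 207.3. Of replication genes, FEN1 was at 53.7, 59.3 and 186.1 and RFC3 at 18.2, 10.4 and 92.1, while E2F2 went the other way at 21.9, 13.5 and 4.7 (counting interval of the log2 difference -3.56 to -1.05).

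Between hESC G1 and S, 1134 regions differed at least 4-fold, 930 higher in S and 204 lower. Quantile normalisation gave 842 higher and 500 lower, and regions with a GC value gave 187 and 134, so the size of the excess depends on the scaling and on the regions used. The count is 292 with the stricter filter and 309 with a pseudocount of 10, so most of these regions are weakly expressed. The 9925 regions with a GC value, all of which carry a gene name, hold 321 of the 1134. Most of the 1134 thus lie among the other regions, which mainly lack a gene name. Nodal and activin targets had a median log2 difference of 0.82 (percentile 100 among random lists, whose members are unrelated, while these targets have an estimated correlation of 0.341), immediate early genes 0.55 (99.9), hypoxia and glycolysis genes 0.30 (98.4) and unfolded protein response genes 0.41 (98.4). Definitive endoderm genes were at -0.54 (percentile 0.19) and DNA methylation and chromatin genes at -0.55 (1.39).

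Within endoderm, TRIM54, a muscle ring finger protein, stood at 9.7 in G1, 126.4 in G1/S and 174.6 in S (log2 difference 4.04, counting interval 3.36 to 5.10). SPOCD1 (2.49), the membrane protein EMP3 (2.44), the sialyltransferase ST3GAL1 (2.36), C2orf54 (2.29), PTPRN (2.22), PHLDA2 (2.21) and the ephrin EFNB2 (2.14) were also higher in S. MYPOP was at 224.4, 121.4 and 56.5 (-1.97) and GLO1 at 122.2, 43.3 and 32.5 (-1.88), with TMEM179 (-1.83), PSMA2 (-1.74), ASTN2 (-1.73), WHSC1 (-1.69), PCSK4 (-1.69) and PELI3 (-1.65) also lower in S. The histone gene HIST1H4C was at 26.2, 13.3 and 186.6 (2.78, counting interval 2.28 to 3.40) and in hESCs at 9.1, 10.4 and 10. The replication clamp PCNA was at 69, 20 and 17.1 (-1.95, counting interval -3.12 to -1.07), and the immediate early gene EGR1 at 87.7, 16.6 and 12. The cell-cycle genes CCND1 and CDKN2A had log2 differences of 1.11 and 1.43, and E2F5 one of -2.30 (20.7, 8.3 and 3.4), with 2 reads in S.

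Between endoderm G1 and S, 604 regions differed at least 4-fold, 239 higher and 365 lower. The stricter filter gave 55 higher and 25 lower, a pseudocount of 10 gave 42 and 19, and quantile normalisation 267 and 194, so the side with more regions depends on the filter, the pseudocount and the scaling. The G1/S and DNA replication list had a median of -0.45 (percentile 0.09), nodal and activin targets -0.61 (0.03), definitive endoderm genes -0.50 (0.22), cholesterol biosynthesis -0.40 (0.42), p53 targets -0.42 (0.98) and pluripotency -0.38 (1.61). Histones were at 0.51 (96.98) and Wnt pathway genes at 0.35 (97.25). The percentiles rank the lists and are no test.

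**Figure D3:**
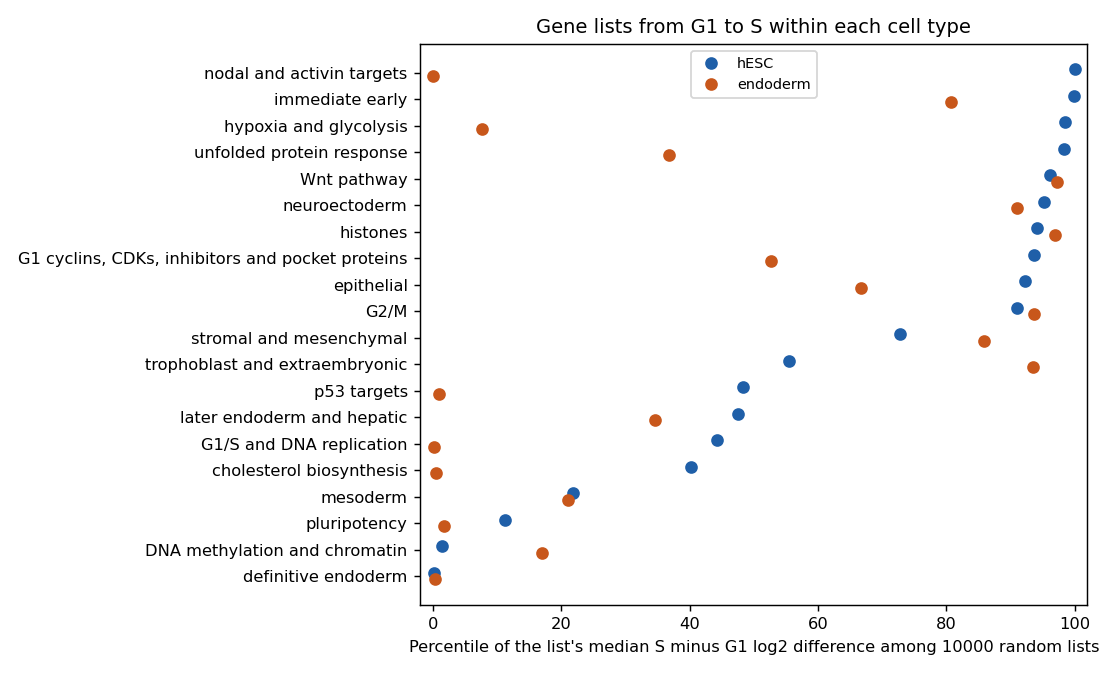
Percentile of each list's median S minus G1 log2 difference among 10000 random lists matched on size and mean level, in hESCs and in endoderm (1 library per phase). Nodal and activin targets lie at opposite ends, at 100 in hESCs and 0.03 in endoderm.

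Set side by side, the S minus G1 differences of the cell types had a Pearson correlation of -0.10 across 14657 regions (95% interval -0.12 to -0.09; Spearman -0.08), where regions are not independent replicates. G1/S minus G1 gave 0.22 and S minus G1/S 0.32. Histone and G2/M genes had medians above 0 in both types, at 0.45 and 0.51 and at 0.17 and 0.13, while replication genes were at -0.06 in hESCs and -0.45 in endoderm. Of the 6 ways to match endoderm phases to hESC phases, the labelled one gave a pooled correlation of 0.17, and the highest, 0.26, came with endoderm G1 and S exchanged. The difference between the types was not tested, as the design leaves no residual for it.

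**Figure D4:**
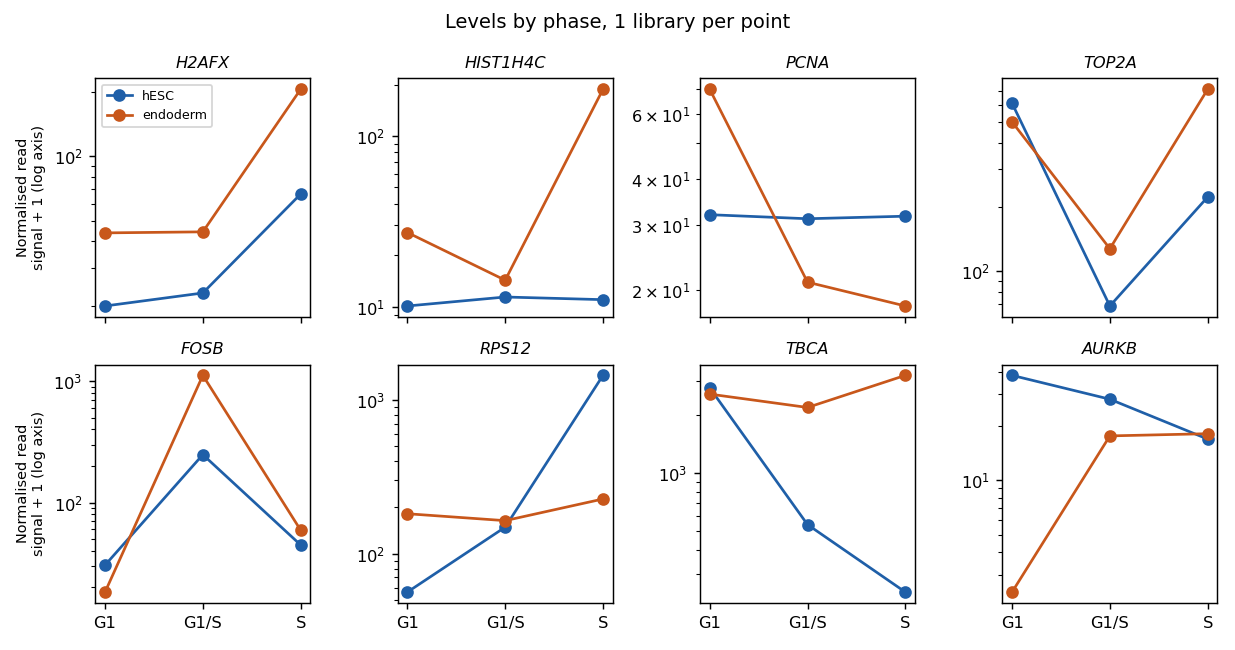
Signal + 1 on log axes in G1, G1/S and S for 8 genes in hESCs and endoderm, 1 library per point. FOSB peaks at G1/S in both types, at 246.8 and 1113, and TBCA goes from 2748.5 to 240.4 in hESCs while it stays between 2176.1 and 3190.5 in endoderm.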

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

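The tests of GC content on the G1/S libraries and on the opposite S minus G1 differences, of RNA from the other cell type, of undifferentiated cells, of copies of POU5F1 and of exchanged labels were chosen after the results they measure were seen; the tests of depth, of GC content at POU5F1 and of other splits were not.

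Nodal and activin targets differed between the cell types from G1 to S. Their median log2 difference was 0.82 in hESCs and -0.61 in endoderm, a gap of 1.43. The gap has 1 library per type and phase behind it and was not tested. Leaving the list aside, 7 named genes went opposite ways by at least 1 on the log2 scale in each type, and these differences were not tested either. The hESC minus endoderm gap was -4.29 for the junction scaffold MAGI1, -4.34 for the actin-severing DSTN, -3.75 for PDGFB, 3.38 for the clamp loader RFC3, -3.18 for the mRNA decay factor ZFP36, -3.89 for EMP3 and -4.10 for the mitotic kinase AURKB, which has 1.4 in endoderm G1, below the limit that a count of 0 allows there (2.07).

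The first pattern weighed is that S minus G1 differences ran weakly opposite in the types (correlation across regions -0.10). With all libraries thinned to 2502792 reads the median correlation over 20 draws was -0.0967 (range -0.11 to -0.09), which argues against unequal depth. After GC correction it was -0.0439, with an interval over chromosomes of -0.06 to -0.02, against -0.06 uncorrected on the same regions. GC content here is a mean over a gene's transcript ends and not that of the region read. The correction therefore cannot settle how much GC content contributes. Exchanging endoderm G1 and S gives a pooled correlation of 0.2556, above the 0.17 as labelled (0.1995 against 0.17 after GC correction, 0.29 against 0.25 uncorrected on the same regions), yet as labelled the medians of histones (0.45 and 0.51) and G2/M genes (0.17 and 0.13) are above 0 and those of replication genes (-0.06 and -0.45) below 0 in both types, none of which was tested, so exchanged labels cannot be told apart from a difference between the types. A phase program that differs between hESCs and endoderm may also account for it, as may hours that differ between the types, and neither was tested.

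The next pattern is that the G1/S libraries deviate from the other phases of their type in like ways (correlation across regions 0.35), although hESC S with endoderm G1 gives 0.39 (0.26 after GC correction, below G1/S), so which pair is most alike depends on the setting, and deviations within a type sum to 0, so the pairs are not independent. The correlation stayed at 0.2989 after GC correction (interval over chromosomes 0.27 to 0.32, from 0.41 on the same regions), so GC content may account for part of it. Whether GC content of the regions themselves accounts for more was not tested. Thinning left it at 0.3365 (range 0.33 to 0.34), which argues against depth. In the 50 regions most specific to the other type, picked in the G1 and S libraries, the G1/S libraries held at most 3.04% of the other type's level (median), against up to 6.63% in the other libraries, which argues against mixed RNA. No list passed for G1/S against G1. The smallest camera adjusted p, 0.0671 (0.745 with an estimated correlation), was for G1/S and DNA replication genes, which tested lower at G1/S. A shared G1/S program and a shared handling of these libraries both stay open.

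The last is POU5F1, at 336 ± 231 in hESCs and 287 ± 28.5 in endoderm while SOX2 fell. Undifferentiated cells left in the endoderm cultures would bring their other transcripts, yet the 50 regions most specific to hESCs stood at a median of at most 6.63% of their hESC level in any endoderm library (upper quartile 11.2%). GC correction left the POU5F1 log2 difference at 0.118, so the trend on GC content of transcript ends does not account for it. A region on chromosome 8 that the table also calls POU5F1 had a mean of 9.81 in endoderm, far below the region on chromosome 6, but how reads with several matches were placed is not given in the sources used here, so reads from copies cannot be told apart from POU5F1 itself. Continued transcription of POU5F1 at day 6 may account for it and was not tested.

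The count of 2125 regions between the types has too few splits behind it for a share under 0.05: 1 of the 10 splits of the 6 libraries, the real one, gave as many (1825 without a phase term), and the highest of the others gave 0.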

How the results depend on the processing

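The tests with a pseudocount of 10, GC correction, both G1/S libraries left out, edgeR and DESeq2 were chosen after seeing the data. Between endoderm and hESCs the count of 2125 regions lay between 1466 and 2780 except for 984 with the stricter filter, which tests fewer regions, and 415 without both G1/S libraries; with 1 library left out it ran from 419 to 2344. For the phase terms, where limma called 0, DESeq2 called 1 (S against G1), 108 (G1/S against G1) and 152 (S against G1/S), and with 1 library left out the counts ran from 0 to 201, 0 to 329 and 0 to 245; a fit that leaves out 1 library has 1 residual degree of freedom and takes the lone library of a phase to vary like the others. The 4-fold counts within types were 292 and 80 with the stricter filter, 309 and 61 with a pseudocount of 10, and on regions with a GC value 321 and 302 uncorrected and 306 and 288 corrected, so the smaller set of regions and not the correction lowers them. The correlation of S minus G1 was -0.121 with a pseudocount of 10, -0.0574 on regions with a GC value and -0.0439 after correction.

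Of 20 lists, 9 passed between the types; 0 passed with an estimated correlation, with or without GC correction, 4 with the stricter filter, 5 without both G1/S libraries and from 5 to 7 with 1 library left out. For S against G1, 6 passed; 0 did with an estimated correlation, with or without GC correction, 3 with the stricter filter, 1 without trend and from 1 to 5 with 1 library left out. Camera was not run with the robust option or the fold minimum, which apply to list members only. The estimated correlation leaves camera 2 degrees of freedom, so the loss of calls under it cannot be laid to correlation among list members. Of 1294 values of named genes between the types under the alternatives that leave out no single library, 1234 kept their side of the threshold (3 of them, with no call, changed sign), 43 lost and 16 gained a call, and 1 turned, DUSP1 at -0.742 with the mean over its regions. Of 534 such values with 1 library left out, 82 lost and 4 gained a call, and no called value turned. Leaving out either library of a phase gives the same difference between the types, so these values are not all separate checks. Within types 9 of 356 values left their counting interval and none changed sign. For G1/S against G1, 19 of 258 values of named genes gained a call, all with DESeq2, and 29 of 120 with 1 library left out; for S against G1 this was 1 of 276 and 1 of 120. The counts of list members that rose or fell between the types are less stable: 72 of 600 moved by more than 1.5 times, of which 23 without both G1/S libraries, 14 without trend, 11 with the stricter filter and 7 without the phase term, and 92 of 240 did with 1 library left out. The numbers given to the libraries stand for their phases, so the phase term is the replicate block and the comparison of the types is paired by phase; 1825 regions passed without it. Libraries of the same number deviate together at G1/S (correlation 0.35) and hardly at G1 (0.0089) or S (0.0848). Where no cause is stated, the cause was not tested. At the depth of these libraries a count of 0 allows a value of up to 1.77 to 5.13. Simulated reads, with depth not varied, recovered 2.99% of 2-fold changes between the types, all placed in better expressed regions.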

Other observations

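Some abundant genes outside the lists differed strongly between the types, and those in this paragraph were chosen after their values were seen. The contractile and stretch-responsive genes MYL4, ANKRD1 and NPPB rose from 310 ± 71.0 to 5791 ± 2190, from 519 ± 162 to 10540 ± 4586 and from 278 ± 190 to 5143 ± 1771 (mean signal ± SD, n = 3 per type), and MYL7 from 3680 ± 147 to 14570 ± 4924. Other genes of heart muscle did not pass, with log2 differences of -0.27 for TNNT2, 0.79 for ACTC1 and 0.19 for MYL3. The membrane protein IFITM1 rose by 2.07 and the protease inhibitor CST1 by 2.91 on the log2 scale. On the lower side were the calcium-binding S100A6 (-2.85), collagen COL7A1 (-2.23) and CGB2 (-4.46), a chorionic gonadotropin gene whose reads are uncertain among near-identical copies.

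Regions without a gene name were not compared with the positions of genes, so some may belong to transcripts of named genes. They made up 4295 of the regions tabulated, of which 680 passed between the types, 291 higher and 389 lower in endoderm. The strongest signal of these was NOVEL_1291 on chromosome 10 (92661777 to 92662025), at 1722 ± 967 in hESCs and 33040 ± 752 in endoderm (log2 difference 4.46 ± 0.35 SE, limma adjusted p = 0.00183).

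Reads in mitochondrial regions made up 3.03%, 2.60% and 1.97% of the hESC libraries in G1, G1/S and S, and 0.716%, 1.29% and 0.522% of the endoderm libraries. Of the 5 mitochondrial regions, those called BC018860 (log2 difference -1.40) and cytochrome b (-1.86) and the unnamed NOVEL_2196 (-2.27) fell in endoderm. NOVEL_2197 was high in both G1/S libraries, at 8072 in hESCs and 9945.3 in endoderm, against values from 686.4 to 1297.2 in the other libraries.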
